A study of Arabidopsis thaliana with 28 samples.

How the data were processed

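RNA was measured by sequencing in nuclear and cytoplasmic fractions of Arabidopsis thaliana rosettes, harvested 14 days old, of the wild type Col-0 and the mutant mos11. Per the labels, fractions were separated by differential centrifugation, a set of external control RNAs was added, ribosomal RNA was depleted during library making and molecular identifiers were read. The labels list 28 samples, which are 18 libraries, some of them sequenced on 2 flow cells. All cytoplasmic libraries and 1 nuclear library of mos11, replicate 2, were on both flow cells.

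The authors deposited one table of raw counts for 30901 genes, with 1 column per library, and every column was matched to its group and replicate by name. All values were whole numbers, and no other columns of values were present. Whether a column sums both flow cells is not stated, and the strand used for counting is not given in the sources used here. The submitters' processing notes name STAR 2.7.8a, Picard, UMI-tools, featureCounts and the TAIR10 genome build, without their roles or the other versions. External controls, organelle genes and small RNA genes were not analysed here. Gene names, positions, exon numbers, transcript lengths and biotypes were taken from the RefSeq annotation of TAIR10.1, in which all 30901 loci were found, 27419 of them protein-coding and 3480 long non-coding. Of these loci, 1487 overlap another on the same strand and 8556 overlap one on the other strand, where reads can be shared.

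Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 18 libraries in 4 groups were fitted together, with TMM normalisation, the default filterByExpr filter, which kept 16207 genes, and quasi-likelihood tests at a Benjamini-Hochberg adjusted p of 0.05. The 5 comparisons were nucleus against cytoplasm in each genotype, mos11 against Col-0 in each fraction, and the difference between genotypes in the nucleus to cytoplasm ratio (an interaction). Positive values mean higher in the nucleus, higher in mos11, or a higher ratio in mos11. Standard errors are approximate, taken as the log2 fold change over the square root of the F statistic. Levels are CPM scaled by the TMM factors, except shares of counts, the nucleus to cytoplasm floors and the cytoplasmic percentages of MOS11 and the genes set beside it, which use raw totals. MOS11 was also compared by a two-sided exact permutation test of log2 CPM.

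Gene groups were 15 lists of known genes and 9 classes by annotation, tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists or over the classes within a comparison, and again with an estimated correlation. Counts for a list are given over all genes tested and adjusted over the list alone. Genes named in the text were chosen by a rule: the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and non-overlapping groups, MOS11, up to 4 members of each list with the smallest p, genes past the threshold among the 10 annotated neighbours on each side of MOS11, and up to 5 genes that moved oppositely in the fractions. Exceptions are named where they occur. The lists, the rule, the tests and most alternative settings were fixed before the data were examined.

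Depth ran from 556016 to 18213517 counts per library. With simulated changes placed on counts of 16207 genes in 5 simulations each, the test recovered 89.4% of 2-fold changes in the nucleus between genotypes, 40.2% in the cytoplasm, 27.6% for the interaction and 64.8% between the fractions of Col-0. Recovery of 4-fold changes was 97.0%, 77.4%, 73.6% and 94.2%, and the share of false calls was 8.44%, 5.67%, 4.70% and 5.89%. The simulations gave each gene the same spread in all groups, with no shared differences between libraries. In the data the biological coefficient of variation was 17.9% and 23.7% in Col-0 nuclei and cytoplasm against 6.13% and 10.8% in mos11. The simulated rates may therefore not hold for the data. A floor of 3 counts over a group was used for genes with no count there, and floors cover counting error only. Replicates were compared pair by pair: their counts differed by 1.18 to 12.4 times the sampling variance, so no library was counted as a copy of another. Replicate numbers were taken to pair the samples only where residuals correlated, while the block was run as an alternative for all 5 comparisons and the reported fit used no pairs: between the fractions of Col-0 the correlation was 0.11 to 0.33, between those of mos11 0.015 to 0.053, and between genotypes -0.09 to 0.10 in the nucleus and -0.02 to 0.036 in the cytoplasm.

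The settings so fixed were median-of-ratios scaling (RLE), no filter on low counts and a filter on CPM (at least 1 CPM in 8 libraries). Also fixed were DESeq2 1.42.0, a test against a change of 1.5-fold, replicate number as a block and a fit of only the groups compared. The omission of each of the 18 libraries in turn was fixed likewise. Runs of 1 flow cell alone, scaling to the external controls and organelle genes could not be used with this table. Alternatives added after the data were seen were group quality weights in limma, subtraction of nuclear carry-over, Col-0 replicate 3 left out in both fractions, and overlapping genes left out. Added likewise were the splits of the replicates into a part to pick genes by the ratio (2 of Col-0 and 3 of mos11, the smallest p in each direction) and a part to measure them. Sequences were aligned with Biopython in Python, and plots were drawn with matplotlib.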

Results

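Nuclear and cytoplasmic RNA was sequenced from rosettes of 14-day-old Arabidopsis thaliana plants of the wild type Col-0 and of mos11. MOS11 encodes a small protein of the nuclear mRNA export machinery, and the series asks which transcripts are held back in the nuclei of the mutant. The count table held 18 libraries in 4 groups, with 4 libraries for each Col-0 fraction and 5 for each mos11 fraction. Total counts were 2547560 to 3719008 in Col-0 nuclei, 1966574 to 18213517 in mos11 nuclei, 556016 to 1160001 in the Col-0 cytoplasm and 907270 to 1280371 in the mos11 cytoplasm. Of 30901 genes, 16207 were tested. The labels number the libraries but do not say whether they came from separately grown plants, so p-values measure the spread between these libraries, which may be technical. That spread was wider in the wild type, with a biological coefficient of variation of 17.9% and 23.7% in Col-0 nuclei and cytoplasm against 6.13% and 10.8% in mos11. Values below are log2 fold changes with an approximate standard error, from 4 Col-0 and 5 mos11 libraries per fraction, and levels are normalised read counts (CPM, scaled to library size) with their SD.

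The first question was whether the MOS11 transcript itself (AT5G02770, chromosome 5, 627034 to 629280, 6 exons, TAIR10.1) differed between the genotypes. In the cytoplasm it stood at 108 CPM ± 18 (SD, n = 4) in Col-0 and at 8.31 CPM ± 2.7 (SD, n = 5) in mos11, which is 13.3-fold lower (log2 fold change -3.73 ± 0.19, adjusted p = 5.8e-13). The mutant level lies near a floor that nuclear carry-over may set, given with the last comparison. The log2 fold change was -4.47 after subtraction of the difference between the floors of the genotypes and -5.74 after subtraction of the whole mutant floor. In the nucleus it stood at 205 CPM ± 15 (SD, n = 4) and 169 CPM ± 9.1 (SD, n = 5), a log2 fold change of -0.28 ± 0.10 that did not pass the threshold (adjusted p = 0.055). Every mos11 library lay below every Col-0 library in both fractions, and the two-sided exact permutation test gave p = 0.0079 in each, the smallest value its 126 splits allow. As shares of raw totals, without the TMM factors used above, the cytoplasmic level of MOS11 was 22.9% of the nuclear level in Col-0 and 2.25% in mos11. On that scale, among 4660 genes with at least 50 CPM in both nuclei, 43.3% had a lower percentage than MOS11 in Col-0 and 0.622% had a lower one in mos11. MOS11 overlaps AT5G02760 on the other strand, and the strand used for counting is not given in the sources used here.

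**Figure D1:**
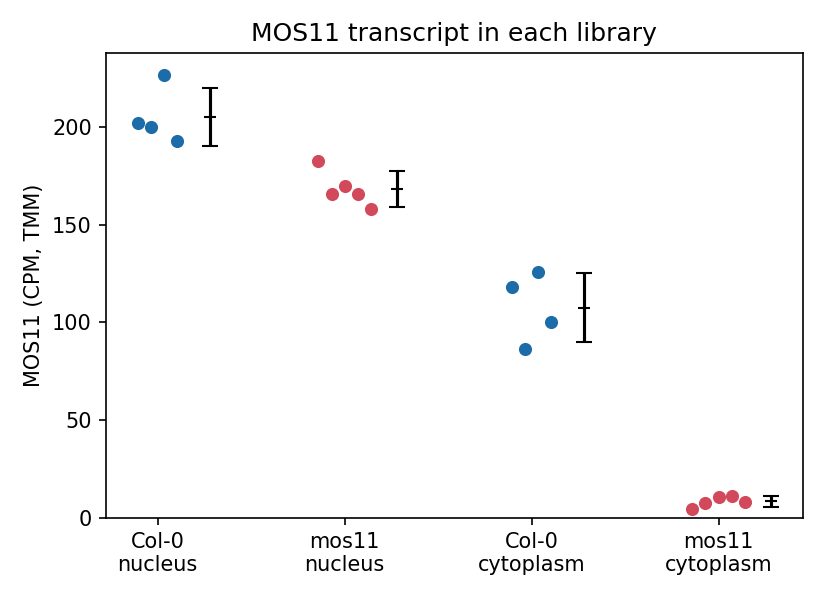
MOS11 level in each library, in TMM-normalised CPM; points are libraries, black marks and bars are group means and SDs. Mean levels were 205 and 169 CPM in the nuclei of Col-0 and mos11, and 108 and 8.31 CPM in the cytoplasm.

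The comparison of the 2 fractions within Col-0 asked which transcripts are enriched in each. Of the Col-0 libraries, the cytoplasmic ones alone were on both flow cells, so fraction and flow cell were not parted. The same held in mos11 except for nuclear replicate 2. Among the largest differences towards the cytoplasm, the metallothioneins MT2B (AT5G02380) and MT3 (AT3G15353), which bind metal ions, were 91.0-fold and 64.6-fold higher there (log2 fold changes -6.51 ± 0.16 and -6.01 ± 0.14), and the cyclophilin ROC1 (AT4G38740) was 67.9-fold higher (-6.09 ± 0.19). All 22 nuclear-encoded photosynthesis genes of the fixed list were higher in the cytoplasm, among them PSAD1, a photosystem I subunit (39.4-fold), and the light-harvesting genes LHCA2 (18.8-fold) and LHCA3 (14.8-fold). The nucleus held more of HA8 (AT3G42640), a plasma membrane proton pump, of the long non-coding RNA AT3G59068 and of AT4G00040, a chalcone synthase relative. HA8 and AT3G59068, which both overlap a gene on the other strand, had no count in the Col-0 cytoplasm; against a floor of 3 counts over that group they were at least 31.6-fold and 124-fold higher in the nucleus. AT4G00040 stood at 120 CPM ± 8.4 in the nucleus and 0.448 CPM ± 0.90 in the cytoplasm (log2 fold change 7.98, but 11.9 without Col-0 cytoplasm replicate 4).

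In all, 11908 genes passed the threshold in Col-0, 6587 higher in the nucleus and 5321 higher in the cytoplasm. The 278 ribosomal protein genes were cytoplasmic as a group, with 262 higher there and 6 higher in the nucleus (median log2 fold change -2.98, camera adjusted p = 1e-64). Histone genes went the same way, with 14 of 19 higher in the cytoplasm (median -2.91, adjusted p = 1.1e-07); the keyword for this class also took in 5 enzymes. Of 171 long non-coding RNAs, 146 were higher in the nucleus (median 3.40, adjusted p = 1.6e-07, but adjusted p = 0.059 with an estimated correlation). Length went with the fraction: the shortest quartile of transcripts had a median of -1.24 and the longest quartile a median of 1.23. Of 28 tested drought, salt and cold genes, 17 were higher in the cytoplasm and 5 in the nucleus (17 and 5 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.69 with an estimated correlation). They included the cold-induced COR15A (71.4-fold), KIN1 (77.8-fold), KIN2 (41.5-fold) and COR47 (16.9-fold). Of the mRNA export factors, 6 were higher in the nucleus and 8 in the cytoplasm out of 25. SAC3A and SAC3B, of the TREX-2 complex, were 8.17-fold and 6.10-fold higher in the nucleus, while the RNA helicase LOS4 and the adaptor ALY4 were 3.55-fold and 3.56-fold higher in the cytoplasm. SR34B, a splicing factor gene, was 50.3-fold higher in the nucleus (log2 fold change 5.65, but 7.38 without Col-0 cytoplasm replicate 3). With the replicate number as a block, which the correlation between fractions allowed in Col-0, 11902 genes passed. The median over all genes was 0.297 and rose by 0.179 with median-of-ratios scaling, so ratios near 1 have no fixed direction.

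RR3 (AT2G41310), annotated as a type-A response regulator of cytokinin signalling, and the long non-coding RNA AT1G05163 took 7.81% and 4.20% of the counts of the Col-0 cytoplasm, against 0.49% and 0.291% in the nucleus. These 2 genes were chosen after their values were seen.

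The same comparison in mos11 gave a closely similar division. MT2B and MT3 were 98.0-fold and 56.6-fold higher in the cytoplasm, ELIP2 (AT4G14690), an early light-induced protein of chloroplasts, was 74.0-fold higher there, and all 22 photosynthesis genes were again cytoplasmic (median -3.57). In the nucleus, SR34B was 45.3-fold higher, the receptor-like protein genes RLP19 and RLP31 were 39.5-fold and 34.1-fold higher, and MOS11 was 20.5-fold higher (log2 fold change 4.35 ± 0.17, but 5.11 and 6.40 after the same subtractions), where it had been 1.87-fold higher in Col-0. Without mos11 cytoplasm replicate 1, SR34B had a log2 fold change of 6.16. Here 12339 genes passed, 6613 higher in the nucleus and 5726 in the cytoplasm. The fold changes of the 16207 genes in the 2 genotypes correlated across genes (Pearson r = 0.921, Spearman rho = 0.948), though genes are not independent replicates. Both genotypes called 5782 genes higher in the nucleus and 4954 higher in the cytoplasm, and 18 went opposite ways. Ribosomal protein genes (266 of 278 cytoplasmic), histone genes (14 of 19 cytoplasmic) and long non-coding RNAs (142 of 171 nuclear, adjusted p = 0.044 with an estimated correlation) divided as in Col-0. Drought, salt and cold genes did not pass as a list (15 cytoplasmic, 7 nuclear, camera adjusted p = 0.054).

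The genotypes were then compared within the nucleus. Among the genes higher in mos11, FRK1 (AT2G19190), a receptor kinase gene induced by microbial patterns, was 10.8-fold higher (3.43 ± 0.33), the ankyrin genes ANK (AT5G54610) and ACD6 (AT4G14400), the second a regulator of salicylic acid defence, were 7.40-fold and 5.07-fold higher, and the transcription factor gene WRKY70 was 4.15-fold higher. Also higher were AT1G72910 (6.21-fold), TIR (AT1G72930, 5.0-fold) and AT1G72920 (4.82-fold, log2 fold change 2.27, but 2.87 without Col-0 nucleus replicate 2), which encode TIR-domain proteins. DFR, of anthocyanin synthesis, was 4.23-fold higher, 4CL3 4.19-fold and ELIP1 4.31-fold. Lower in mos11 were HB-2 (AT4G16780) and PAR1 (AT2G42870), both induced by shade, at 6.81-fold and 5.42-fold, and ASN1 (AT3G47340), the dark-induced asparagine synthetase, which fell from 902 CPM ± 442 (SD, n = 4) to 201 CPM ± 63.9 (SD, n = 5). The protein kinase gene AT2G31010 and the splicing factor gene AT1G60200 were 5.56-fold and 4.05-fold lower, the first at -2.48 but -1.85 without Col-0 nucleus replicate 3, the latter with a narrow error (-2.02 ± 0.12).

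In the nucleus 3254 genes passed the threshold, 1482 higher and 1772 lower in mos11, and 377 and 282 of them by more than 2-fold. The larger side was not stable, with 1721 higher and 1319 lower without mos11 cytoplasm replicate 4 and 2082 and 1931 in a fit of these groups alone. Of 18 tested immunity and salicylic acid genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.59; the camera adjusted p was 2.2e-05 (adjusted p = 0.19 with an estimated correlation). SARD1, an activator of salicylic acid synthesis, was 2.39-fold higher, and PR1, a marker of that response, was 3.08-fold higher at 3.24 CPM ± 0.905 against 1.04 CPM ± 0.374. Of 28 drought, salt and cold genes 8 rose and none fell (10 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.0013, adjusted p = 0.28 with an estimated correlation). ZAT10 and ZAT12, zinc finger repressors of stress responses, were 3.64-fold and 2.95-fold higher, and the calcium-binding RD20 was 2.83-fold higher. Abscisic acid genes went both ways, 9 up and 9 down of 34 (10 and 9 adjusted over the list alone): CYP707A2, which breaks the hormone down, was 2.73-fold higher and NCED3, which makes it, 2.0-fold lower. Among clock genes RVE1 (3.01-fold), PRR9 (1.84-fold) and LHY (1.43-fold), which peak in the morning, were higher, and PRR7, a neighbour of MOS11, was 1.86-fold lower. Of the 25 export factors 3 fell, SAC3B by 2.02-fold, SAC3A by 1.35-fold and ALY3 by 1.34-fold. The flowering regulators SPL3 and FD were 3.12-fold and 1.72-fold lower. Guard cell markers MYB60 (1.76-fold) and FAMA (1.60-fold) were higher and the potassium channel KAT1 was 1.51-fold lower, a call that ended without Col-0 nucleus replicate 4 (-0.48, adjusted p = 0.072); the list did not pass (camera adjusted p = 0.051). No class of genes by length, introns or function passed with the preset correlation. Against a change of 1.5-fold, 425 genes passed. The Col-0 libraries stood apart from each other, with ASN1 from 551 to 1550 CPM in Col-0 nuclei. Col-0 replicate 3 minus replicates 1 and 2 correlated at -0.584 with mos11 minus Col-0 replicate 4, across 12246 genes not picked by genotype. A state shared by Col-0 replicates 3 and 4 would alone give a negative value, so this does not tie the genotype differences to such a state. Without both fractions of Col-0 replicate 3, 3098 genes passed, and 2740 of the 3254 were among them.

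In the cytoplasm, mos11 had less of the messages of photosynthesis. Of 22 nuclear-encoded photosynthesis genes 18 fell and none rose (19 and 0 adjusted over the list alone; median -0.54, camera adjusted p = 7.8e-23, adjusted p = 0.023 with an estimated correlation). The light-harvesting genes LHCA3 (1.81-fold, -0.86 ± 0.08), LHCA1 (1.72-fold) and LHCA2 (1.69-fold) and the photosystem subunit gene PSAD1 (1.68-fold) were among them. The dark- and starvation-induced ASN1 and SEN1 (AT4G35770) were 18.9-fold and 11.7-fold lower, with a wide spread in the wild type: ASN1 stood at 1490 CPM ± 1550 (SD, n = 4) in Col-0 and 78.6 CPM ± 22.4 (SD, n = 5) in mos11. The thioredoxin WCRKC1 and the nucleotide exchange factor Fes1B were 13.1-fold and 11.8-fold lower. Without Col-0 cytoplasm replicate 3 these 4 log2 fold changes shrank. ASN1 went from -4.24 to -3.26, SEN1 from -3.55 to -2.48, WCRKC1 from -3.71 to -2.77 and Fes1B from -3.55 to -2.41. Without mos11 cytoplasm replicate 1, WCRKC1 was at -4.36. Higher in mos11 were ANK (11.6-fold), 4CL3 (6.89-fold), the glucosyltransferase UGT76E11 (6.87-fold) and PR1 (6.41-fold). The immunity and salicylic acid list did not pass (2 higher and 1 lower of 18, 3 and 1 adjusted over the list alone, camera adjusted p = 0.37). PR1 stood at 7.15 CPM ± 7.06 (SD, n = 4) in Col-0 and 37.3 CPM ± 3.07 (SD, n = 5) in mos11. Its log2 fold change was 2.68, and 3.35 without Col-0 cytoplasm replicate 2. ANK was at 3.54, and at 4.92 without replicate 4 of that group. 4CL3 was at 2.78, and at 3.45 without its replicate 1. HA8, with no count in the Col-0 cytoplasm, was at least 3.68-fold higher against the floor of 3 counts over that group.

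Here 2014 genes passed, 976 higher and 1038 lower in mos11. This division was 852 and 1228 with median-of-ratios scaling, 934 and 1460 with DESeq2, 922 and 911 without Col-0 cytoplasm replicate 1 and 857 and 762 without mos11 cytoplasm replicate 4. Ribosomal protein genes were lower as a group, 75 of 278 with none higher (median -0.25, camera adjusted p = 3.4e-15, adjusted p = 0.0096 with an estimated correlation), as were histone genes (5 of 19, or 8 lower and 2 higher adjusted over the class alone, median -0.35, adjusted p = 0.0057, adjusted p = 0.018 with an estimated correlation). The shortest quartile of transcripts had 520 lower and 123 higher, and the longest quartile 85 lower and 399 higher. Touch and jasmonate genes had 3 lower and 1 higher of 15 (6 and 1 adjusted over the list alone; median -0.29, camera adjusted p = 0.0067, adjusted p = 0.69 with an estimated correlation): the calmodulin-like TCH3 and the cell wall enzyme TCH4 were 3.43-fold and 5.68-fold lower, and the defensin PDF1.2 was 8.96-fold higher. TCH4 was at -2.51, and at -3.16 without mos11 cytoplasm replicate 4, and PDF1.2 at 3.16, and at 4.25 without Col-0 cytoplasm replicate 1. Clock genes had 3 higher of 13 (6 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.18 with an estimated correlation), among them LHY (2.77-fold) and CCA1 (2.14-fold). The cold- and drought-induced COR15A, RAB18 and LEA7 were 4.13-fold, 3.96-fold and 6.05-fold lower (LEA7 at -2.60, but -1.95 without Col-0 cytoplasm replicate 4), while the galactinol synthase GOLS2 was 2.02-fold higher; that list went both ways, 4 up and 5 down of 28. ABI1, a phosphatase that restrains abscisic acid signalling, was 2.49-fold higher, and the hormone's receptor genes PYR1 and PYL4 were 1.62-fold and 1.54-fold lower. PDF1, an epidermal gene, was 2.15-fold lower and ABCG12, a wax transporter of the epidermis, 1.92-fold higher. Of the 25 export factors MOS11 alone passed. Between the fractions, 464 genes were higher in mos11 in both, where 89.2 would be shared by chance if the fractions were independent, 386 were lower in both (113 likewise) and 27 went opposite ways; fold changes correlated across genes at r = 0.408. The fractions of Col-0 replicates correlated, so part of this sharing need not come from genotype. Without both fractions of Col-0 replicate 3, 1772 genes passed, of which 1452 were among the 2014. Against a change of 1.5-fold, 210 passed.

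**Figure D2:**
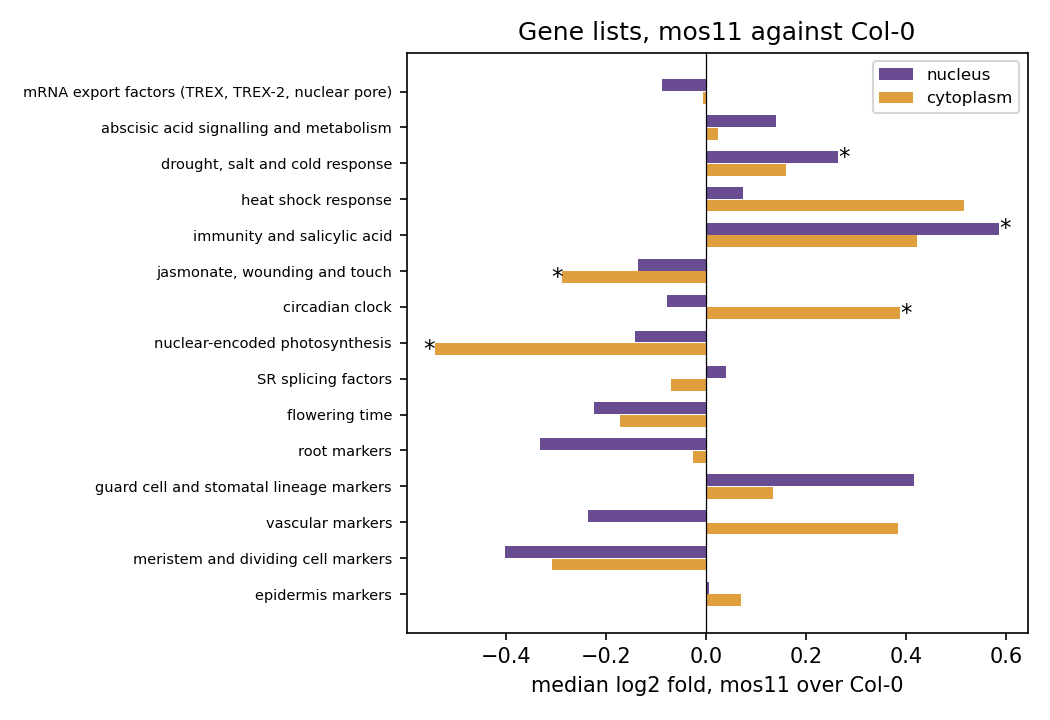
Median log2 fold change of mos11 over Col-0 for the 15 fixed gene lists, in the nucleus and in the cytoplasm; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Photosynthesis genes had a median of -0.14 in the nucleus and -0.54 in the cytoplasm.

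The last comparison asked for which transcripts the ratio of nucleus to cytoplasm differed between mos11 and Col-0; this ratio depends on stability as well as export. MOS11 had the largest rise among the named genes (log2 fold change of the ratio 3.45 ± 0.23, 10.9-fold, adjusted p = 1.8e-10). Its size depends on carry-over, at 4.186 and 5.456 after subtraction of the difference between the floors given below and of the whole mutant floor. MOS11 is the gene changed in the mutant, so an effect of the allele on its own transcript was not parted from export. The ratio also rose for UBC11 (AT3G08690), a ubiquitin-conjugating enzyme, at 5.54-fold (2.47 ± 0.27), the plastid enzyme gene G6PD3 (5.28-fold), TCH3 (3.83-fold), AT3G10020 (3.58-fold) and TCH2 (2.69-fold). UBC11 moved in opposite directions in the fractions, from 6.34 CPM ± 0.627 to 12.0 CPM ± 1.61 in the nucleus and from 67.1 CPM ± 21.4 to 21.6 CPM ± 2.80 in the cytoplasm. Its close relative UBC12 also differed between the genotypes, and whether the 2 genes share reads was not tested. The ratio fell for PIP5K5 (AT2G41210), a lipid kinase gene (-3.41 ± 0.70, but -8.78 without Col-0 cytoplasm replicate 1), for the starch synthase gene SS4 (-2.32 ± 0.43), for AT2G35750, whose locus also holds 2 snoRNA genes (-2.14 ± 0.20), and for SAC3B (-1.31 ± 0.24).

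The ratio of 256 genes passed, 107 higher and 149 lower in mos11. With replicate number as a block, supported by the correlation between fractions in Col-0 but not in mos11, 629 passed, 326 higher and 303 lower. Of the 107, 101 were cytoplasmic in Col-0, with a median of 3 exons and 1327 bases, and of the 149, 128 were nuclear in Col-0, with a median of 8 exons and 3235 bases. Since Col-0 values enter both the class and the ratio, genes were also picked by their ratio on part of the replicates and classed by the sign in the others (means of 6 splits): 85% of those picked for a rise were cytoplasmic in Col-0, against 43.7% of all tested genes, and 80.8% of those picked for a fall were nuclear, against 56.3%. Photosynthesis genes had 9 higher of 22 (16 higher and 2 lower adjusted over the list alone), with a median of 0.43 and a camera adjusted p of 2.6e-12 (adjusted p = 0.19 with an estimated correlation), LHCA3 and LHCA1 rising 1.56-fold each. PSAF, of photosystem I, rose 1.87-fold, and FBP, an enzyme of sucrose synthesis, rose 2.51-fold. Ribosomal protein genes had 4 higher and none lower (median 0.24, camera adjusted p = 7.4e-12, adjusted p = 0.018 with an estimated correlation). The longest quartile of transcripts had 108 lower and 3 higher (camera adjusted p = 8.3e-11), and the shortest quartile 8 lower and 58 higher (adjusted p = 6.2e-08). Over all genes, ratios lay nearer to even in mos11 (slope of mutant on wild-type ratios 0.877, given below). Such a slope alone raises the ratio of groups that are cytoplasmic in Col-0 and lowers that of nuclear ones. Whether any group moved beyond it was not tested. Touch and jasmonate genes (2 higher of 15, camera adjusted p = 0.0059, adjusted p = 0.50 with an estimated correlation) and drought, salt and cold genes (1 higher of 28, adjusted p = 0.0064, adjusted p = 0.35 with an estimated correlation) leaned higher. Clock genes leaned lower (1 lower of 13, adjusted p = 0.023, adjusted p = 0.35 with an estimated correlation), with LHY at -0.96 ± 0.22. Of these, LHY did not pass without Col-0 nucleus replicate 4 (-0.86, adjusted p = 0.054). For 176 of the 256 genes the signs were opposite in the fractions and at least 1 fraction passed, and 26 of these passed in both. Of the 25 export factors MOS11 rose and SAC3B fell.

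This count was the least stable of the 5: it was 163 without Col-0 nucleus replicate 4, 154 without Col-0 cytoplasm replicate 4, 147, 160 and 152 without mos11 nucleus replicates 2, 3 and 5, and 159 and 132 without mos11 cytoplasm replicates 2 and 4, and 8 genes passed against a change of 1.5-fold. With median-of-ratios scaling the division turned to 142 higher and 109 lower, and it was 317 and 261 with DESeq2 and 150 and 149 without Col-0 nucleus replicate 2; simulated 2-fold changes of the ratio were recovered in 27.6% of cases; among the 709 genes above 200 CPM in both nuclei, the lowest 1% had a cytoplasmic level under 0.82% of the nuclear one in Col-0 and under 1.87% in mos11; with that difference taken out of the mos11 cytoplasm, 170 genes passed.

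**Figure D3:**
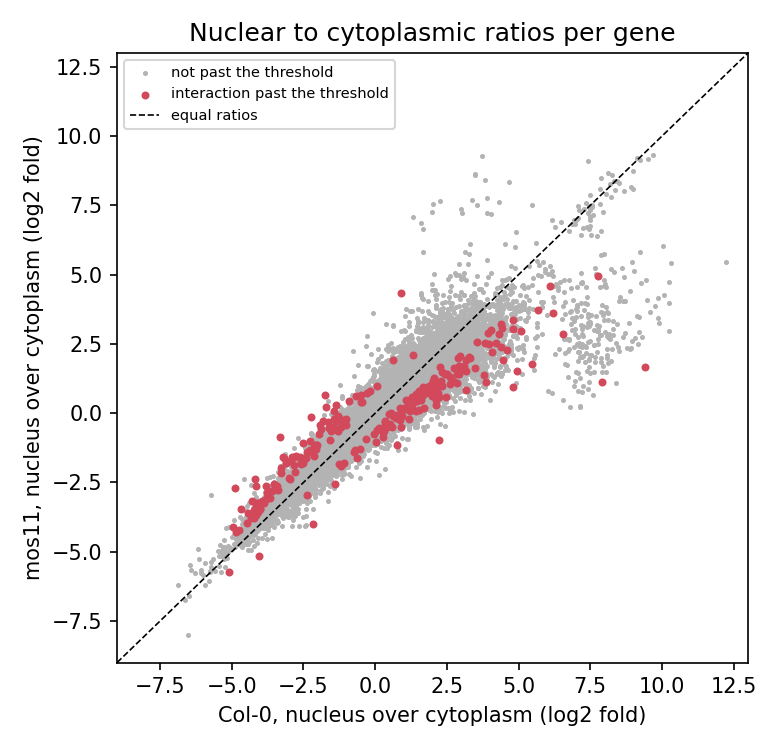
Nucleus over cytoplasm log2 fold change of each of 16207 genes in Col-0 (x axis) and mos11 (y axis); red points are the 256 genes whose ratio differed, and the dashed line marks equal ratios. Most red points on the right lie below the line and most on the left lie above it.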

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

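The tests of ratio, library axis and RR3 in this part were chosen after the results were seen, and the counts of other splits were planned, except the count with the replicate block.

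A single library lay far from the rest of its group in 6 of 48 checks, where chance gives about 1 in 20 groups. Total counts were 18213517 in mos11 nucleus replicate 2 against 1970000 to 2720000 in the other 4, and 907270 in mos11 cytoplasm replicate 3 against 1210000 to 1280000. Of all nuclear libraries, only mos11 nucleus replicate 2 was on both flow cells, and whether a column sums both is not stated. QQS stood at 1.11 CPM in mos11 cytoplasm replicate 4 and at 0 in the other 4 libraries, and UBC12 at 0.269 CPM in Col-0 nucleus replicate 1 and at 0 in the other 3; beside groups at 0 any count stands apart, so these 2 say nothing against chance. PR1 stood at 1.59 CPM in Col-0 nucleus replicate 4 against 0.806 to 0.931, and RAB18 at 113 CPM in mos11 cytoplasm replicate 3 against 161 to 169.

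The nucleus to cytoplasm ratio of 256 genes differed between the genotypes by the interaction test, 107 higher and 149 lower in mos11. Named genes whose interaction passed had these log2 fold changes when the ratio was higher: MOS11 3.45, UBC11 2.47, G6PD3 2.40, RAB18 2.16, AT5G51190 2.09, TCH3 1.94, AT3G10020 1.84, AT1G70820 1.69, ERF6 1.63, IPT3 1.57, TCH2 1.43, FBP 1.33, AT1G67870 1.12, PSAF 0.91, PYR1 0.83, LHCA4 0.73, LHCA3 0.64, LHCA1 0.64, LHCB6 0.61, RSZ32 0.58. When it was lower they were: AT1G35510 -3.68, PIP5K5 -3.41, AT3G61010 -2.82, KMS1 -2.74, AT2G14255 -2.59, AT5G22850 -2.55, ERL2 -2.43, SS4 -2.32, AT4G07070 -2.32, AT2G35750 -2.14, NCED3 -1.39, SAC3B -1.31, LHY -0.96. Of these, RAB18, AT5G51190, AT1G70820, ERF6, IPT3, LHCA4, LHCB6, RSZ32, AT1G35510, AT3G61010, KMS1, AT2G14255, AT5G22850, ERL2, AT4G07070, NCED3 and LHY lost their call when 1 library or another was left out, and ERL2 and NCED3 also with median-of-ratios scaling. Some folds moved by over 1.5 times: without Col-0 cytoplasm replicate 3, AT1G35510 was at -7.53, KMS1 at -3.72 and AT5G22850 at -3.94, without replicate 2 AT3G61010 was at -3.56, and without replicate 1 PIP5K5 was at -8.78. Gene groups whose interaction passed the set test had these adjusted p-values: drought, salt and cold response 0.0064, jasmonate, wounding and touch 0.0059, circadian clock 0.023, nuclear-encoded photosynthesis 2.6e-12, shortest quartile of transcripts 6.2e-08, longest quartile of transcripts 8.3e-11, ribosomal proteins 7.4e-12. With an estimated correlation the 4 lists did not pass (0.35, 0.50, 0.35 and 0.19 in that order), and the 3 classes did (0.00026, 3.6e-06 and 0.018). Whether these groups moved beyond the slope over all genes, given below, was not tested.

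Other splits of the same libraries gave fewer calls than the real groups in every comparison. A chance division of these libraries can thus be excluded for each, though in Col-0 only when the pairing of its fractions is left aside. Since the labels do not say whether libraries came from separately grown plants, chance differences between plants or batches are not excluded. Between the fractions of Col-0, 1 of 35 splits called as many genes as the real one (10931, highest other 0). Between the fractions of mos11, 1 of 100 splits called as many genes as the real one (12117, highest other 0). Between the genotypes in the nucleus, 1 of 100 splits called as many genes as the real one (4013, highest other 402). Between the genotypes in the cytoplasm, 1 of 100 splits called as many genes as the real one (1529, highest other 91). For the interaction, 1 of 100 splits called as many genes as the real one (256, highest other 43), and with the replicate block and both fractions of a replicate kept together, 1 of 100 did (629, highest other 142). In the 4 comparisons of 2 groups the fit held those groups alone. The splits of Col-0 libraries that part all 4 replicate pairs are 8, too few for a share under 5% (1 called as many, 10931, highest other 0).

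A first pattern was that nucleus to cytoplasm ratios lay nearer to even in mos11: the slope of mutant on wild-type ratios, allowing for error in the latter, was 0.877 (0.856 to 0.896 when a library was left out). Thinning every library to 556016 counts left a slope of 0.896, which argues against depth as the whole cause of the slope, but 88 genes passed there instead of 256. In 6 splits of the replicates, 107 genes picked for a rise of the ratio on part of them were measured in the others. Their median log2 fold change in the cytoplasm was -0.431 ± 0.083 (mean and SD over splits), and ranged from -0.512 to -0.313. Dilution by nuclear RNA at the whole mutant floor of 1.87% allows -0.0272. This argues against nuclear RNA carried into the mutant cytoplasm as the whole cause of the rises. In the nucleus, the median log2 fold change of these genes between genotypes ranged from 0.0631 to 0.47. Carry-over of cytoplasmic RNA into the nuclear fractions was not tested. The splits reuse the same libraries, so SDs over splits are not standard errors. Genes that passed when picked ranged from 1 to 107 of 107 for rises and from 1 to 112 of 149 for falls. For the falls, 149 genes picked alike had a median ratio change of -0.588 ± 0.11 in the other replicates and -0.53 ± 0.086 after that floor was subtracted, which argues against carry-over as the whole cause; of the 149 calls on all libraries only 74 were kept after the subtraction, for a reason not tested (median -1.09 before and -0.995 after, median error 0.243 and 0.250, slope 0.933 after). Minima of 50 or 500 CPM gave mutant floors of 2.88% and 1.57%, and subtracting 1.5 or 2 times the floor difference gave slopes of 0.921 and 0.942, so carry-over may account for part of the calls, while a difference between the genotypes in the stability or export of RNA stays open, untested.

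A second pattern was a correlation between differences among the Col-0 nuclear libraries and the genotype difference. It was taken across 12246 genes with a mean log2 CPM of at least 3, not picked by genotype. Col-0 replicate 3 minus replicates 1 and 2 correlated at -0.584 with mos11 minus Col-0 replicate 4. With replicates 3 and 4 exchanged it was -0.413, and in the cytoplasm the values were -0.161 and -0.164. A state shared by Col-0 replicates 3 and 4 alone would give negative values wherever mos11 lies. A growth or harvest state that varied between plants may contribute to the genotype differences, but these values do not decide it. For harvest at another time of day the clock genes do not decide: in the nucleus the 5 morning genes had a median log2 fold change of 0.68 and the 4 evening genes of -0.376, between the values set for and against it. None of the evening genes passed in either fraction. In the cytoplasm they ranged from -0.054 to 0.65, and the morning genes from 0.86 to 1.47. The mutation as the cause of such a state stays open, since the labels do not say how the genotypes were placed or harvested.

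The last pattern was the weight of RR3 in the Col-0 cytoplasm, at 78100 raw CPM against 4900 in the nucleus. The highest of the other type-A regulators, ARR4, reached 0.0436% of RR3 there, so they did not share its weight. Without a cytokinin treatment or baseline, and with the source of the RR3 counts open, this does not test a cytokinin response. A candidate source is a short non-coding RNA copied in the last exon of RR3: that exon aligns to AT1G15405 (292 bases), which overlaps AT1G05163 (42000 raw CPM) on the same strand and has no level of its own in the table, with 173 identities and a score of 139, and 0 of 1000 random tested genes aligned as well (highest score 33). AT2G31141, which holds a closer copy (score 312), was also cytoplasmic, at 2850 against 403 raw CPM. Reads were not analysed here, so their position in RR3 stays open.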

How the results depend on the processing

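Group quality weights, carry-over subtraction, omission of Col-0 replicate 3 and omission of overlapping genes were chosen after seeing the data; the cause of the changes below was not tested unless stated. The 5 counts stayed within 1.5 times their value under no filter, the filter on CPM and RLE. Both filter settings tested more genes than the main fit (26481 and 19283 against 16207), so a stricter filter was not tried. The MOS11 fold changes kept their direction and side of the threshold under RLE and the block. Between the fractions, counts changed when overlapping genes were left out, with fewer genes tested (7910 in Col-0, 8225 in mos11). Between genotypes, a test against 1.5-fold asks for more by construction (425 genes in the nucleus, 210 in the cytoplasm, 8 for the interaction). The cytoplasm count was 1233 with the replicate block, which leaves out mos11 replicate 5, and 1094 with quality weights. For the interaction, the count was 629 with the block, 578 with DESeq2, which gave no adjusted p for 6913 genes, 128 with quality weights, 170 after carry-over subtraction and 134 without overlapping genes; the block kept 253 of the 256 genes, DESeq2 245 and the quality weights 116. RLE raised the median of all genes by 0.179 between the fractions of Col-0 and by 0.234 in mos11. With the block, the nucleus had 1364 higher and 1110 lower. With 1 library left out, the counts ranged from 11437 to 12249 and from 11568 to 12923 between the fractions of Col-0 and mos11, from 2256 to 3634 in the nucleus, from 1507 to 2222 in the cytoplasm and from 132 to 333 for the interaction. Nuclear MOS11 ranged from -0.31 to -0.22 and passed without Col-0 cytoplasm replicate 2 or 3 or mos11 cytoplasm replicate 1; cytoplasmic MOS11 ranged from -3.86 to -3.57. Of 33 named interaction genes, 17 lost their call in at least 1 omission and 2 under RLE, and none reversed; of 57 named in the cytoplasm and 69 in the nucleus, 11 and 8 lost their call in at least 1 omission.

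With an estimated correlation, list calls ended between fractions for drought, salt and cold genes in Col-0 (0.69), in the nucleus for drought, salt and cold (0.28) and immunity genes (0.19), in the cytoplasm for touch and jasmonate (0.69) and clock genes (0.18), and for the interaction for drought (0.35), touch and jasmonate (0.50), clock (0.35) and photosynthesis genes (0.19). Long non-coding RNAs in Col-0 lost theirs (0.059). Calls appeared for the second quartile of transcripts by length (0.033 in Col-0, 0.031 in mos11, 0.0075 for the interaction), the third quartile (0.00028 in the cytoplasm, 0.0056 for the interaction) and genes with introns (0.0097 in the nucleus). With the block, calls appeared for drought genes in mos11 (0.022), guard cell markers in the nucleus (0.049), immunity genes for the interaction (0.0079) and long non-coding RNAs in the nucleus (0.024). Lists that did not pass turned direction without passing: export factors in mos11 (0.99) and for the interaction (0.74), vascular markers in mos11 (0.87) and epidermis markers in the cytoplasm (0.95). With the block and an estimated correlation together, the gains with the block did not pass (0.39, 0.7, 0.2 and 0.5 in the order given). Calls ended for photosynthesis genes in Col-0 (0.084), mos11 (0.21) and the cytoplasm (0.48), for genes without introns in Col-0 (0.072), for ribosomal proteins in the cytoplasm (0.058) and for histones in mos11 (0.063) and the cytoplasm (0.068). New calls appeared there for long non-coding RNAs in the interaction (0.047) and the second quartile of transcripts in the cytoplasm (0.04). Under RLE long non-coding RNAs passed in the nucleus (0.042). Runs of 1 flow cell, scaling to external controls, organelle genes and the small RNA classes were not run. Simulated 2-fold changes were found in 89.4% of cases in the nucleus between genotypes, 40.2% in the cytoplasm and 27.6% for the interaction. The simulations gave each gene the same spread in all groups and did not part depth from spread.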

Other observations

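Apart from MOS11, 3 further genes, chosen after their values were seen, differed between the genotypes. QQS (AT3G30720), an orphan gene that affects starch content, stood at 103 CPM ± 15.1 (SD, n = 4) in Col-0 nuclei and 1.01 CPM ± 0.509 (SD, n = 5) in mos11 nuclei, and MRD1 (AT1G53480) at 12.4 CPM ± 2.31 and 0.229 CPM ± 0.199. UBC12 (AT3G08700), a close relative of UBC11 with a nearby locus number, went the other way, at 0.0672 CPM ± 0.134 in Col-0 nuclei and 6.58 CPM ± 0.443 in mos11 nuclei. Whether reads are shared between UBC11 and UBC12 was not tested. In the cytoplasm QQS stood at 6.80 CPM ± 5.27 and 0.222 CPM ± 0.497, MRD1 at 15.3 CPM ± 4.41 and 0, and UBC12 at 0 and 4.51 CPM ± 3.31.

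Of the 20 annotated neighbours of MOS11, 13 were tested, and 3 passed between the genotypes in each fraction. Of all tested genes, 20.1% passed in the nucleus and 12.4% in the cytoplasm. The cytoplasmic calls for AT5G02710 and GSTL1 ended when certain single libraries were left out. GSTL1, a glutathione transferase, was 2.98-fold higher in mos11 nuclei, and AT5G02830 was 1.73-fold higher in the nucleus and 2.94-fold higher in the cytoplasm.

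Other lists did not pass between the genotypes, which does not show that they were unchanged (heat shock genes had a median of 0.515 in the cytoplasm). In the nucleus, heat shock genes had 2 higher and 1 lower of 9 (camera adjusted p = 0.43), SR splicing factors 1 lower of 19 (0.96), root markers 1 lower of 7 (0.42), vascular markers 1 lower of 9 (0.64), meristem markers 1 lower of 6 (0.25) and epidermis markers 1 higher and 1 lower of 5 (0.88). Nuclear photosynthesis genes had 2 higher and 6 lower of 22 (0.11), and clock genes 4 higher and 1 lower of 13 (0.43). Touch and jasmonate genes had 2 higher and 5 lower of 15 there (0.64), and flowering genes 2 lower of 9 (0.32). In the cytoplasm, heat shock genes had 1 higher of 9 (0.15), SR factors 1 lower of 19 (0.38), flowering genes 1 lower of 9 (0.37), root markers 1 lower of 7 (0.88), guard cell markers 1 higher of 7 (0.66), vascular and meristem markers 0 of 9 and 0 of 6 (0.38 and 0.66) and epidermis markers 1 higher and 1 lower of 5 (0.91).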
